A study of Caenorhabditis elegans with 24 samples.

How the data were processed

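The intensity values are the processed values the authors deposited, a single table of 22548 probe sets and 24 columns, each of which belongs to a sample (0 columns of no sample). Per the labels, biotin-labelled material was hybridized to single-channel Affymetrix arrays after amplification from 500 pg of total RNA with a TargetAmp kit (2007) or from 100 ng with an Affymetrix kit of 2 cycles (2008). The deposited intensities are on a linear scale with values below 0, which points to a background subtraction; the probe set summary method, the background method and any scaling are not given in the sources used here. Strain, treatment, year and replicate number come from the sample titles and descriptions. Whether replicates were separate cultures is not stated.

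Groups, comparisons, tests, 32 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined, from the labels alone. The scale rule fixed then asked for quantile normalization if the medians of the log2 columns spanned more than 0.5, and they spanned 2.62. Values were quantile normalized over all 24 arrays on the linear scale, values below 0 were set to 0, and log2(value + 32) was taken, so the lowest possible value is 5.00. The design had not foreseen deposited values below the negative of that constant, of which there were 11243 (2.08%); of normalized values 15.5% were at or below 0. No probe set carried a control ID (0), and all were tested.

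The model was fitted with limma (3.58.1, R 4.3.3) as a mean per group of strain and treatment plus a term for year, over all 24 arrays, with 17 residual degrees of freedom and 2.24 prior ones. Moderated p-values are two-sided and adjusted by Benjamini-Hochberg over all probe sets, and the limit for a call was an adjusted p of 0.05. UV effects were UV minus control within a strain, their average over strains, and their difference between a mutant and N2. Strain effects were mutant minus N2 controls. The year difference came from a model with a mean for each strain, treatment and year. Direction counts give the arrays of the first group, of 4, that differ from the mean of the other group of the same year in the direction of the change.

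Probe sets were named from the supplied table: 20766 carried 1 gene, 887 several and 895 none. Symbols were updated from the supplied gene table, which changed 0. A gene was represented by the probe set naming it alone with the highest mean over all arrays, which gave 17118 genes. In each comparison the 8 largest rises and 8 largest falls with the same sign in both years were named, where none passed the 5 genes with the smallest p, and 3 members with the smallest p from each called list; xpa-1, glp-1, cep-1, egl-1, ced-13 and the nucleotide excision repair genes were always reported in UV comparisons. The genes next to xpa-1 were taken from the order of the supplied gene table.

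Gene lists held 15 to 177 measured genes and were tested by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 32 lists within a comparison. The tests camera with an estimated correlation and fry were run as alternatives. Members were counted at an adjusted p under 0.05 over all probe sets and adjusted over the list alone. The lists share some genes.

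Alternatives fixed in advance were a replicate block, no year term, a year term per strain, each year alone, values as deposited, median centring, the dimmest 40% left out, trend and robust variances, array weights, the compared groups alone, an adjusted p of 0.01, a fold of 1.5, log2(value + 1), log2(value + 100), each array left out, and the mean over probe sets for lists. Added after the data were seen were quantile normalization within each year, scaling to the 75th percentile, 1 weight per year, the mean of the major sperm protein list as a covariate, and a replicate block for the year difference.

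Whether equal replicate numbers pair arrays was checked by correlating, across genes and within a year, the difference between replicates 1 and 2 in the groups compared. In N2 the correlation was 0.10 in 2007 and 0.31 in 2008, and in glp-1 0.16 and 0.46, so these comparisons counted as paired and were refitted with the replicate block, which called 0 and 0 probe sets. No label states that equal numbers share a culture, and the N2 value of 2007 barely passed the limit of 0.1. In xpa-1 it was -0.19 and 0.34, for xpa-1 against N2 controls -0.13 and 0.30, and for glp-1 against N2 controls -0.044 and 0.31, and these counted as unpaired.

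The fit was tested on simulated data with the group sizes and spread of the real arrays, 22548 probe sets, 50 of them changed per size. With the N2 comparison 22% of changes of 1 on the log2 scale were called, 58% of 1.5, 76% of 2 and 92% of 3, and with the glp-1 comparison 22%, 64%, 80% and 94%. With a separate spread per year the shares were 26%, 62%, 76% and 94%, and 30%, 66%, 78% and 94%. Of 22171 unchanged probe sets 10, 4, 4 and 2 were called in the 4 runs. A shift of 0.5 in the xenobiotic list was called in each run, with 0 of the 31 other lists. The simulated noise was independent between probe sets, so these runs do not test the list calls where genes are correlated. In the real arrays 100% of the other splits for UV in N2 called at least 1 list.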

Results

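Transcript levels were measured in whole young adult Caenorhabditis elegans of 3 strains, all reared at 25°C and used 24 h after the vulval crescent stage. The strains were wild-type N2, a deletion mutant of xpa-1 and a point mutant of glp-1. The gene xpa-1 encodes the nematode counterpart of human XPA, a factor of nucleotide excision repair, the pathway that removes UV photoproducts from DNA. The gene glp-1 encodes a Notch receptor that germ line stem cells need in order to proliferate, and glp-1 mutants raised at 25°C lack most of their germ line. Animals of each strain were left untreated or were exposed to 50 J/m2 of UVC radiation (emission peak 254 nm) and frozen 3 h later. Each group was measured in 2 separate years, 2007 and 2008, on 2 arrays per year, so that 24 arrays fell into 6 groups of 4. The labels do not state whether a year's replicates came from separate cultures, so p-values measure only the spread between these samples. That spread is pooled over years and includes year effects that differ by group. All values below are background-corrected intensities of 22548 probe sets, scaled between arrays and given as log2(value + 32), and each gene was represented by its brightest probe set. Where a group lies near the lowest possible value of 5.00, the size of a change depends on the added 32 and no fold is given.

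The arrays of both years differed in signal. Total RNA of 500 pg was amplified in 2007 and of 100 ng in 2008, with different kits. The median intensity of an array was 4.24 to 8.42 in 2007 and 68.9 to 190.5 in 2008, and the share of probe sets above an intensity of 100 was 5.85% to 19.5% in 2007 and 45.0% to 58.0% in 2008. Arrays of the same group and year correlated with Spearman coefficients of 0.757 to 0.882 in 2007 and 0.953 to 0.977 in 2008, across probe sets, which are not independent replicates. The median SD within a group was 0.54 in 2007 and 0.20 in 2008. Every group was present in both years, so year entered the model as a block. The number of arrays limits the precision, and the median standard error of a difference between 2 groups of 4 was 0.33 on the log2 scale.

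The xpa-1 transcript was lower in every xpa-1 mutant array than in every N2 array, and the glp-1 transcript lower in every glp-1 array than in every array of the other strains. The xpa-1 transcript was at 9.55 ± 0.41 (SD, n = 4) in N2 controls and at 9.56 ± 0.53 after UV. In the xpa-1 mutant it was at 5.71 ± 0.59 in controls and 5.15 ± 0.14 after UV, near the lowest possible value of 5.00, with single arrays between 5.00 and 6.59. The position of the xpa-1 probe set relative to the deletion is not given in the sources used here; a probe outside the deleted part would check nothing, but the signal was lost in all 8 mutant arrays. In glp-1 animals the xpa-1 transcript was at 6.84 ± 0.34 in controls and 6.71 ± 1.15 after UV, with single arrays at 5.00 to 7.41, so its level does not tell glp-1 from xpa-1 animals. The glp-1 transcript was at 10.53 ± 0.09 in N2 controls, 10.79 ± 0.30 after UV, 10.5995 ± 0.14 in xpa-1 controls and 10.77 ± 0.26 after UV. It was at 5.64 ± 0.85 in glp-1 controls and 5.87 ± 1.02 after UV, where the array glp-1 UV 2008-1 stood highest at 7.39. A point mutation removes no probe target, so the low glp-1 signal is a transcript level and not a check of the lesion.

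**Figure D1:**
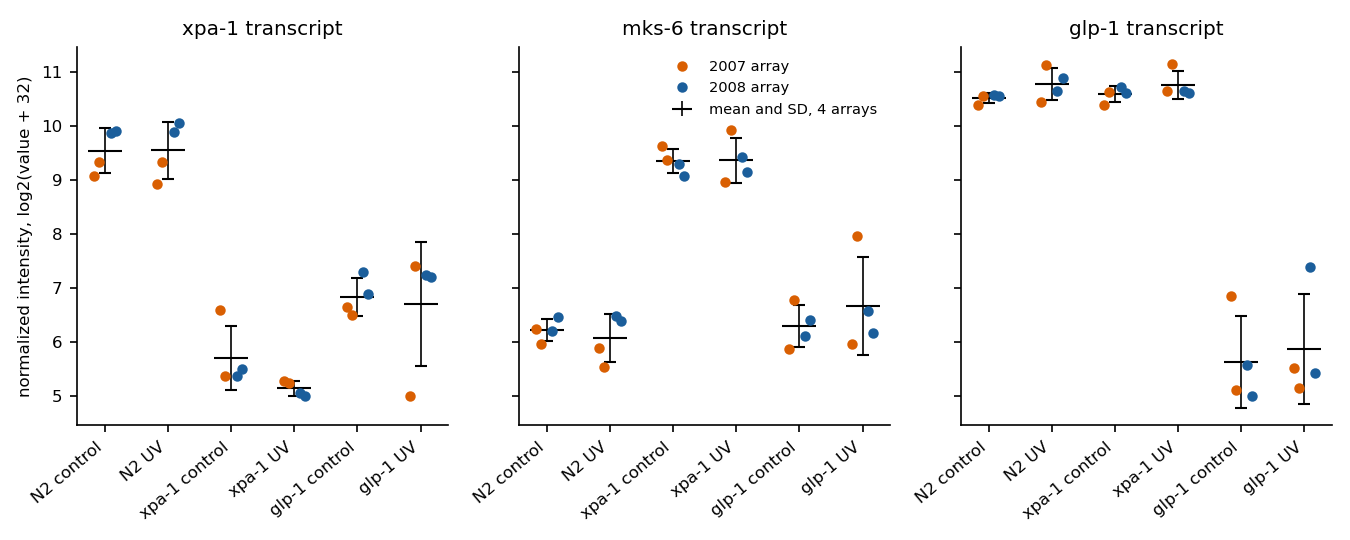
Normalized intensity (log2(value + 32)) of the transcripts xpa-1, mks-6 and glp-1 in each array by group, with 2007 and 2008 arrays as separately coloured points and the mean with SD of 4 arrays. The xpa-1 transcript lay at 5.71 ± 0.59 in xpa-1 controls against 9.55 ± 0.41 in N2 controls, mks-6 lay at 9.35 ± 0.22 against 6.23 ± 0.20, and glp-1 lay at 5.64 ± 0.85 in glp-1 controls against 10.53 ± 0.09.

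The comparison of untreated xpa-1 and N2 animals asked what loss of xpa-1 alters without added damage. Of 22548 probe sets 2 were called at a limma adjusted p under 0.05, and they belonged to neighbouring genes. The xpa-1 transcript itself fell by 3.84 on the log2 scale (SE 0.40, adjusted p = 1.93e-04, lower in 4 of 4 mutant arrays). The transcript of mks-6, which encodes a protein of the ciliary transition zone and is the next gene in the annotation order, rose by 3.13 (SE 0.34, adjusted p = 2.38e-04, higher in 4 of 4), from 6.23 ± 0.20 to 9.35 ± 0.22 (n = 4). The other measured genes among the 5 on either side did not pass, with values of -0.37 for crml-1, -0.088 for K07G5.4, -0.081 for fecl-1, -0.095 for hpo-11, 0.0070 for K07G5.5 and 0.11 for let-522 (adjusted p = 1.0 each). At an unadjusted p under 0.05 stood 842 probe sets, against 1127.4 that chance alone would give. Of the fixed genes, cep-1, the nematode p53, was at -0.021, the cell death activators egl-1 and ced-13 were at 0.88 and 0.055, and glp-1 was at 0.074, none of which passed. One list of 32 was called, that of body wall and pharyngeal muscle genes, with a median of -0.22 over 37 members (camera adjusted p = 0.0238; adjusted p = 0.9261 with an estimated correlation). No muscle member passed, over all genes or adjusted over the list alone, and its members nearest to passing were the titin-like ttn-1 at -0.89, the actin act-4 at -0.27 and the myosin light chain mlc-1 at -0.55. In the nucleotide excision repair list xpa-1 was the 1 member called, also when adjusted over the list alone. Scaling changed these calls. On values as deposited, where the median of all genes stood at -0.14, the 1 probe set called was that of haf-6, with xpa-1 at -3.28 (SE 0.68, adjusted p = 0.6926) and mks-6 at 2.01 (SE 0.47, adjusted p = 1.0). With median centring 0 were called, with xpa-1 at -3.17 (SE 0.62) and mks-6 at 2.12 (SE 0.36), and with quantile normalization within each year 0, at -3.13 (SE 0.699) and 2.28 (SE 0.38). In these 3 fits both changes shrank and both errors grew, while each deposited control intensity of 2008 still lay apart: xpa-1 at 19.7 and 23.1 in the mutant against 1569.3 and 2239.1 in N2, and mks-6 at 696.2 and 1505.2 against 84.8 and 140.7. A year term per strain, which is no scaling, gave 54 calls. The muscle call was absent without N2 control 2007-1 (-0.052), xpa-1 control 2007-1 (0.015), xpa-1 control 2008-2 (-0.12) or N2 control 2008-1 (-0.071).

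The comparison of untreated glp-1 and N2 animals asked which transcripts depend on the germ line. The transcripts that fell most were sip-1, a small heat shock protein (-7.51, SE 0.49, adjusted p = 2.63e-10), cbd-1 and cpg-2, eggshell proteins (-7.36 and -6.85), and rme-2, the oocyte receptor for yolk (-7.34). The linker histone gene hil-5 (-7.02), the B-type cyclin cyb-2.1 (-6.84), T22D1.5 (-7.02) and trcs-1 (-6.87) followed. The largest rises were in dhs-26, a short-chain dehydrogenase (5.73, SE 0.82, adjusted p = 1.12e-05), T22B7.7 (5.04), C17H12.6 (4.94), the cytochrome P450 gene cyp-35B1 (4.91, SE 0.18, adjusted p = 8.54e-14), pals-6 (4.44), the C-type lectin clec-60 (4.36) and the ferritin ftn-1 (4.30). The gene scl-20, a target of the daf-16 pathway, also rose, by 5.11 (SE 0.51); it stood at the lowest possible value of 5.00 in every N2 control array, from normalized intensities listed at 0, and at 10.11 ± 0.995 in glp-1 controls (n = 4). All of these moved in the same direction in 4 of 4 glp-1 arrays.

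In total 8511 probe sets passed, 4450 higher and 4061 lower in glp-1, which stand for 6797 of 17118 genes (3612 higher, 3185 lower). Of the called probe sets 52.3% were higher, against 27.7% on values as deposited and 58.1% with scaling to the 75th percentile. The median of all genes stood at 0.065, at 0.31 with median centring, 0.15 with 75th percentile scaling and -0.093 as deposited, so each change is relative to such a shift. The 2007 arrays alone called 4296. The glp-1 transcript fell by 4.89 (SE 0.40, adjusted p = 6.27e-09), xpa-1 by 2.71 (SE 0.40, adjusted p = 1.47e-05) and cep-1 by 3.78 (SE 0.25, adjusted p = 3.73e-10), the last with a second probe set at -0.22. The cell death genes egl-1 (-0.38) and ced-13 (-0.13) did not pass. Of the 32 lists 22 were called by camera, 10 up and 12 down; 12 were called with an estimated correlation and 25 by fry.

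Germ line and proliferation lists fell in glp-1. Of 39 oocyte and maternal genes 35 fell, 0 rose and 4 did not pass (median -5.35, adjusted p = 8.17e-27), among them egg-1, an egg surface receptor for fertilization (-6.34), cpg-1 (-5.90) and oma-1, which controls oocyte maturation (-5.61). Of 44 mitotic and meiotic germ line genes 42 fell and 2 did not pass (median -3.33, adjusted p = 1.52e-28), with deps-1 of germ granules at -6.68 and the chromosome axis genes htp-3 and htp-1 at -5.52 and -5.32. In these lists, adjusted over the list alone, 35 and 43 fell. Among 43 cell cycle and DNA replication genes 39 fell, over all genes and adjusted over the list alone, and 4 did not pass (median -3.95, adjusted p = 8.17e-27), with the ribonucleotide reductase rnr-1 at -5.92, cdk-1 at -5.89 and the primase pri-1 at -5.34. Transcription and RNA polymerase II genes fell in 21 of 28 cases, 22 adjusted over the list alone, and 7 did not pass (median -1.33, adjusted p = 1.08e-08), with the TFIID subunit taf-5 at -1.91, rpb-6 at -1.57 and emb-5 at -1.31.

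Repair transcripts were lower in animals with little germ line. Of 21 measured nucleotide excision repair genes 14 fell, 0 rose and 7 did not pass (median -1.22, adjusted p = 4.15e-07), and 15 fell when adjusted over the list alone. The DNA ligase lig-1 was at -4.06, the replication protein A subunit rpa-1 at -2.88 and cdk-7, a kinase of TFIIH, at -2.0, although the 3 other cdk-7 probe sets ranged from -2.55 to -0.016. Of 38 other DNA repair genes 37 fell, also adjusted over the list alone, and 1 did not pass (median -2.63, adjusted p = 1.09e-22), with the mismatch repair gene msh-2 at -4.78, the nuclease subunit slx-1 at -3.36 and the Fanconi gene fcd-2 at -2.93. Of 32 damage checkpoint and apoptosis genes 20 fell, 2 rose and 10 did not pass (median -1.22, adjusted p = 8.66e-07), the same numbers as adjusted over the list alone. Among them were gld-1, a translational regulator of germ cells, at -5.63 (a second probe set at -0.78) and the checkpoint clamp loader hpr-17 at -4.08. These lists, and the germ line, cell cycle and transcription lists, were also called with an estimated correlation (adjusted p = 8.13e-06 to 0.0011).

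Immune, metabolic and intestinal transcripts were higher in glp-1, where regulation was not told apart from a larger somatic share of RNA. Of 41 innate immunity genes 34 rose, 0 fell and 7 did not pass (median 1.83, adjusted p = 1.35e-08), 35 adjusted over the list alone, with the antimicrobial peptide abf-2 at 4.23, irg-5 at 4.20 and the MAP kinase kinase sek-1 at 1.16. Of 177 xenobiotic metabolism genes 98 rose, 5 fell and 74 did not pass (median 1.2, adjusted p = 6.73e-10), 100 and 6 adjusted over the list alone, with cyp-37A1 at 2.45 and ugt-23 at 2.15. Of 33 insulin signalling and daf-16 target genes 23 rose, 4 fell and 6 did not pass (median 1.72, adjusted p = 5.44e-05), 24 and 4 adjusted over the list alone, with the insulin-like ins-7 at 2.21 and dod-23 at 1.79. Of 40 lipid metabolism and yolk genes 25 rose, 0 fell and 15 did not pass (median 0.80, adjusted p = 2.47e-05), 27 and 1 adjusted over the list alone, with the desaturase fat-5 at 3.83, the lipase lipl-2 at 3.78 and the lipid regulator sbp-1 at 1.78. Of 28 intestine genes 20 rose and 8 did not pass (median 1.09, adjusted p = 5.71e-07), 22 adjusted over the list alone, with far-3 at 4.09, the metallothionein mtl-1 at 3.86 and the receptor itr-1 at 1.82. Each of these 5 lists was called with an estimated correlation (adjusted p = 0.0011 to 0.0146).

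The other called lists lost their call with an estimated correlation. Proteasome genes fell in 24 of 33 cases and 9 did not pass (median -0.72, adjusted p = 2.93e-07; adjusted p = 0.1297 with an estimated correlation), 26 adjusted over the list alone, with rpn-1 at -1.03, rpt-3 at -0.95 and rpn-8 at -0.78. Ribosome biogenesis and translation genes showed 13 falls, 3 rises and 9 not passing (median -0.72, adjusted p = 5.48e-04; adjusted p = 0.0989 with an estimated correlation), 15 and 4 adjusted over the list alone, with nol-56 at -1.83, fib-1 at -1.78 and the cap-binding ife-1 at -1.52. Ribosomal protein genes fell in 29 of 72 cases and 43 did not pass (median -0.36, adjusted p = 2.24e-06; adjusted p = 0.4299 with an estimated correlation), 40 adjusted over the list alone, with rpl-11.1 at -3.62, rps-19 at -0.43 and rpl-27A at -0.51, but with 75th percentile scaling the list turned to 0.40 (adjusted p = 0.0072), rps-19 to 0.31 and rpl-27A to 0.25. Of 27 ubiquitin ligase adaptors 14 fell, 7 rose and 6 did not pass (median -0.61, adjusted p = 0.0456; adjusted p = 0.0663 with an estimated correlation), 15 and 7 adjusted over the list alone, with the Skp1-related skr-2 at -4.01, skr-15 at -3.43 and skr-9 at -3.38. Of 20 mitochondrial stress genes 7 fell, 3 rose and 10 did not pass, also adjusted over the list alone (median -0.46, adjusted p = 0.0460; adjusted p = 0.0663 with an estimated correlation), with hmg-5 at -2.24, hsp-6 at -1.49 and pdr-1 at -0.82. The last 2 lists were not called without N2 control 2007-2 (ubiquitin ligase adaptors -0.59, mitochondrial stress -0.47), glp-1 control 2007-2 (-0.57, -0.49), N2 control 2008-2 (-0.63, -0.42) or glp-1 control 2008-2 (-0.62, -0.37).

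Stress and somatic tissue lists made up the remaining calls. Of 34 oxidative stress genes 20 rose, 3 fell and 11 did not pass, also adjusted over the list alone (median 0.59, adjusted p = 0.0075; adjusted p = 0.0705 with an estimated correlation), with the glutathione transferases gst-10 and gst-13 at 2.26 and 2.14. Of 15 osmotic and wounding response genes 12 rose and 3 did not pass, 13 adjusted over the list alone (median 1.60, adjusted p = 0.0019; adjusted p = 0.1006 with an estimated correlation), with hmit-1.1 at 3.42, cnc-2 at 2.25 and dcar-1 at 1.60. Neuronal genes rose in 16 of 43 cases and 27 did not pass, also adjusted over the list alone (median 0.72, adjusted p = 0.0018; adjusted p = 0.1464 with an estimated correlation), with the syntaxin unc-64 at 1.97, the neuropeptide flp-18 at 1.67 and sbt-1 at 1.34. Of 23 spermatheca and somatic gonad genes 11 rose, 1 fell and 11 did not pass, also adjusted over the list alone (median 0.69, adjusted p = 0.0107; adjusted p = 0.0651 with an estimated correlation), with nid-1 at 1.65, inx-9 at 1.41 and fos-1 at 1.32. Of 37 body wall and pharyngeal muscle genes 7 rose, 2 fell and 28 did not pass, 7 and 0 adjusted over the list alone (median 0.60, adjusted p = 0.0352; adjusted p = 0.6278 with an estimated correlation), with unc-98 at 2.92, cpn-3 at 1.52 and tni-4 at 1.19. The muscle list was not called without N2 control 2007-2 (0.41), glp-1 control 2007-2 (0.48) or N2 control 2008-2 (0.56).

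The 10 lists that were not called were heat shock and cytosolic chaperones (4 rose and 11 fell of 24, adjusted p = 0.0984), endoplasmic reticulum stress (4 and 1 of 22, 0.7182), oxidative phosphorylation (10 and 4 of 41, median 0.18 against a mean of -0.0065, 0.4672). To these came glycolysis and citrate cycle (15 and 6 of 37, 0.13) and histones (9 and 9 of 35, median 0.11 against a mean of -0.44, 0.6779). The others were sperm (2 and 4 of 31, 0.4130), the major sperm protein family (0 and 1 of 23, 0.3047), embryonic zygotic genes (2 and 8 of 30, 0.0573), cuticle collagens (28 and 9 of 146, 0.0797) and moulting and epidermis (8 and 11 of 39, 0.4672). Adjusted over the list alone, glycolysis held 15 and 8, endoplasmic reticulum stress 3 and 1, sperm 1 and 3, the major sperm protein family 0 and 0, collagens 19 and 6, moulting 8 and 12, and the other 4 lists kept their numbers. The major sperm protein median was -2.01 within 2007 and 0.90 within 2008.

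**Figure D2:**
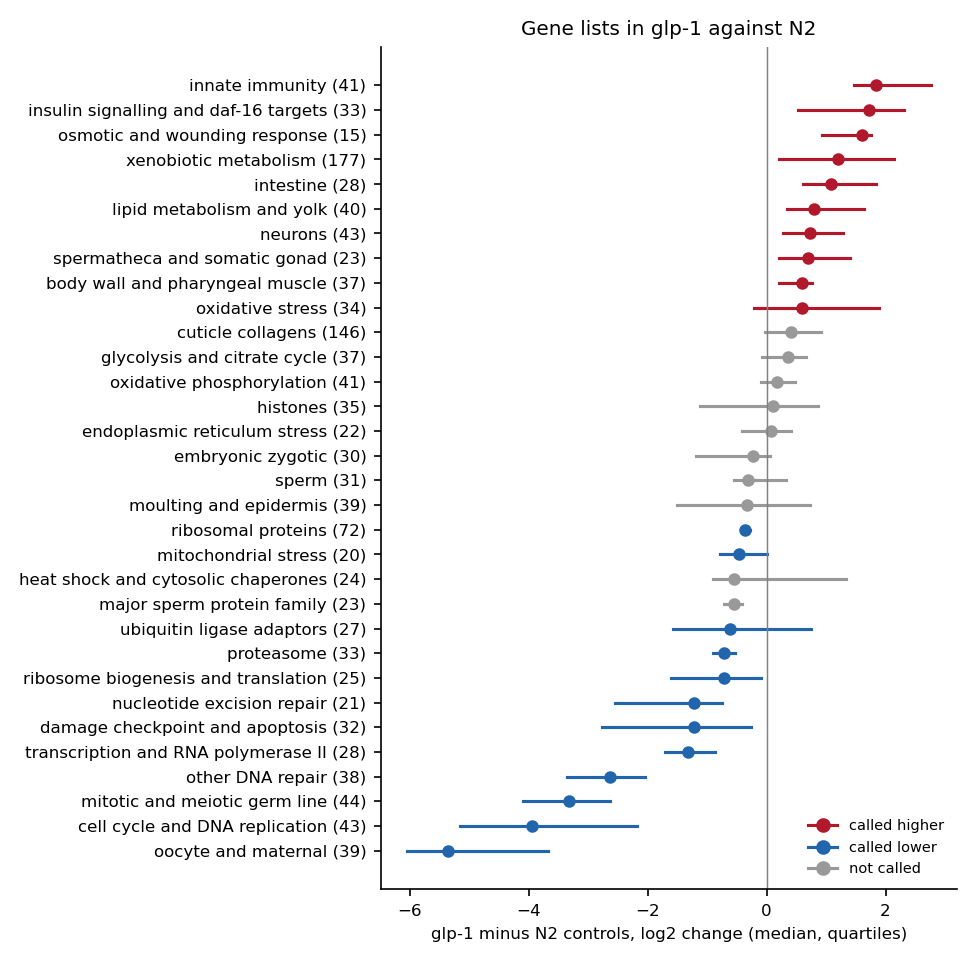
Median log2 change of each gene list between glp-1 and N2 controls (points, with quartiles as bars, 4 arrays per group). Oocyte and maternal genes had a median of -5.35 and innate immunity genes of 1.83, while ribosomal protein genes at -0.36 turned to 0.40 with 75th percentile scaling.

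The UV comparison in N2 asked which transcripts respond to UVC in wild-type animals within 3 h. No gene passed, and the genes with the smallest p were all higher after UV in 4 of 4 arrays. The cation-transporting ATPase gene catp-3 was at 8.04 ± 0.59 (n = 4) in controls and 10.26 ± 0.60 after UV, a difference of 2.23 (SE 0.38, adjusted p = 0.1414). F54B8.4 differed by 2.39 (adjusted p = 0.4154), the UDP-glucuronosyltransferase ugt-26 by 1.94, Y73C8C.8 by 1.58 and the F-box gene fbxa-163 by 1.44 (adjusted p = 1.0 each). The cell death activator egl-1, a known target of p53, was 1.11 higher (SE 0.54, adjusted p = 1.0, 4 of 4 arrays), ced-13 was 0.49 higher, and cep-1, glp-1 and xpa-1 were at 0.23, 0.26 and 0.0070. The limma count was 0 of 22548 with 611 probe sets at an unadjusted p under 0.05, fewer than the 1127.4 of chance. Array weights called 25, 1 weight per year 6, a trend with robust variances 2, and a fit of the N2 arrays alone 1.

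Immune transcripts were the N2 list with the largest shift after UV. Of 41 innate immunity genes 30 were higher and 11 lower, the list was called as up with a median of 0.32 (camera adjusted p = 5.83e-05; adjusted p = 0.4216 with an estimated correlation). Of its genes 0 passed over all genes and 1 rose when adjusted over the list alone. The infection response genes irg-1 and irg-2 were 2.19 and 2.06 higher, and zip-2, which encodes a transcription factor that acts on irg-1, was 1.07 higher; irg-1 was at 5.59 ± 0.44 in controls and 7.78 ± 0.12 after UV (n = 4). The list median was 0.63 within 2007 and 0.0000 within 2008. Proteasome genes were called as up (median 0.12, adjusted p = 3.43e-04; adjusted p = 0.4686 with an estimated correlation), with rpn-13 at 0.41, rpn-8 at 0.25 and pbs-4 at 0.24. Other DNA repair genes were called as up too (median 0.14, adjusted p = 0.0239; adjusted p = 0.4216 with an estimated correlation), with parp-2 at 0.36, the polymerase polk-1 at 0.30 and fcd-2 at 0.18. Intestine genes were called as down (median -0.23, adjusted p = 0.0023; adjusted p = 0.4216 with an estimated correlation), with the metallothionein mtl-2 at -0.60, the acid phosphatase pho-1 at -0.52 and dct-16 at -0.50. Neuronal genes were called as down as well (median -0.21, adjusted p = 0.0037; adjusted p = 0.4485 with an estimated correlation), with the synaptotagmin snt-1 at -0.99, the kinesin unc-104 at -0.90 and sbt-1 at -0.51. So were cuticle collagens (median -0.15, adjusted p = 0.0040; adjusted p = 0.4686 with an estimated correlation), with col-131 at -1.08, and muscle genes (median -0.17, adjusted p = 0.0359; adjusted p = 0.7168 with an estimated correlation), with unc-89 at -0.56. Ribosomal protein genes were called as down (median -0.089, adjusted p = 3.43e-04; adjusted p = 0.7168 with an estimated correlation), with rps-18 at -0.36, but stood at 0.12 on values as deposited and at 0.092 with median centring. No member of these 7 lists passed, over all genes or adjusted over the list alone; of 177 xenobiotic metabolism genes 4 rose when adjusted over the list alone while that list was not called (adjusted p = 0.3466). Without 1 array the calls were absent as follows: muscle without control 2007-1 (-0.082), UV 2007-2 (-0.016), control 2008-1 (-0.11) or UV 2008-2 (-0.14), and collagens without control 2007-1 (-0.097), UV 2007-2 (-0.074) or UV 2008-2 (-0.078). Other repair was not called without UV 2007-2 (0.068), control 2008-1 (0.096), control 2008-2 (0.14) or UV 2008-2 (0.11), proteasome without control 2008-1 (0.071) or UV 2008-2 (0.069), and neurons without control 2008-1 (-0.15) or UV 2008-2 (-0.14). The intestine call was absent without control 2008-1 (-0.16) and the ribosomal call without UV 2007-2 (-0.017). Of 32 lists 8 were called, 4 without N2 UV 2007-2, and 3 without N2 control 2008-1 or N2 UV 2008-2; fry called 0 (smallest adjusted p = 0.6013).

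The UV comparison in xpa-1 asked which transcripts respond where nucleotide excision repair is missing. The F-box gene fbxa-163 rose by 2.93 (SE 0.33, adjusted p = 7.88e-04), from 5.75 ± 0.65 to 8.68 ± 0.72 (n = 4), and catp-3 rose by 2.24 (SE 0.38, 4.71-fold, adjusted p = 0.0386), from 8.11 ± 0.78 to 10.34 ± 0.30. The ammonium transporter gene amt-4 fell by 2.62 (SE 0.39, adjusted p = 0.0162), from 8.83 ± 0.17 to 6.21 ± 0.53. F25E5.8 fell by 1.58 (adjusted p = 0.0386), H40L08.2 by 1.49 (SE 0.20, adjusted p = 0.0036), the patched-related ptr-20 by 1.38 (adjusted p = 0.0414) and C05C8.7 by 1.1 (adjusted p = 0.0360), and each of the 7 moved the same way in 4 of 4 arrays. The p53 pathway genes did not pass, with ced-13 at 0.90 (unadjusted p = 0.0311 by limma), egl-1 at 0.052 and cep-1 at 0.049, and glp-1 and xpa-1 were at 0.17 and -0.56. The 7 calls (2 higher, 5 lower) stood among 1307 probe sets at an unadjusted p under 0.05. The count was 2 without control 2007-1, UV 2007-1 or control 2008-1, 3 without UV 2007-2, UV 2008-1 or UV 2008-2, and 4 without control 2007-2, and in each of these fbxa-163 and H40L08.2 were still called. The catp-3 call was absent in all of them but the fit without control 2007-2, and amt-4 was not called without control 2007-1, UV 2007-2, UV 2007-1 or control 2008-1. On values as deposited, where the median of all genes stood at 0.14, and with median centring 0 were called, as with quantile normalization within each year or the compared groups alone. The count was 1 from the 2007 arrays, 2 with log2(value + 1), 3 without a year term, 4 with 75th percentile scaling, 19 from the 2008 arrays, 149 with 1 weight per year and 262 with array weights.

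Immune genes were again the list with the largest shift in xpa-1. Of 41 innate immunity genes 34 were higher after UV and 7 lower, the list was called as up with a median of 0.53 (adjusted p = 2.26e-08; adjusted p = 0.0653 with an estimated correlation). In it 5 rose when adjusted over the list alone while 0 passed over all genes. The values were 2.41 for irg-2, 1.33 for the C-type lectin clec-85 and 1.27 for zip-2, and the list median was 0.55 within 2007 and 0.36 within 2008. Ubiquitin ligase adaptors were called as up (median 0.11 over 27 members, adjusted p = 0.0340; adjusted p = 0.0653 with an estimated correlation), with 1 rise adjusted over the list alone. The largest shifts there were in the Skp1-related skr-3 (1.74) and skr-4 (0.82) and the cullin cul-6 (1.0), and the call was absent without control 2007-2 (median 0.075), control 2008-1 (-0.014) or UV 2008-2 (0.079). Neuronal genes were called as down (median -0.19 over 43 members, adjusted p = 0.0450; adjusted p = 0.7158 with an estimated correlation), with 1 fall adjusted over the list alone. Values were the touch neuron tubulin mec-7 at -1.12, the acetylcholine synthesis gene cha-1 at -1.35 and the GABA synthesis gene unc-25 at -1.34. The neuronal call was absent without control 2007-2 (-0.16), UV 2007-2 (-0.092), control 2008-1 (-0.12) or UV 2008-2 (-0.19). The 3 calls became 7 without control 2007-1, 9 without UV 2007-1, and 1 without control 2007-2, control 2008-1 or UV 2008-2; fry called 0 (smallest adjusted p = 0.0784). Lists not called held 2 rises in xenobiotic metabolism, 2 falls in intestine, and 1 fall each in somatic gonad and embryonic zygotic genes when adjusted over the list alone.

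**Figure D3:**
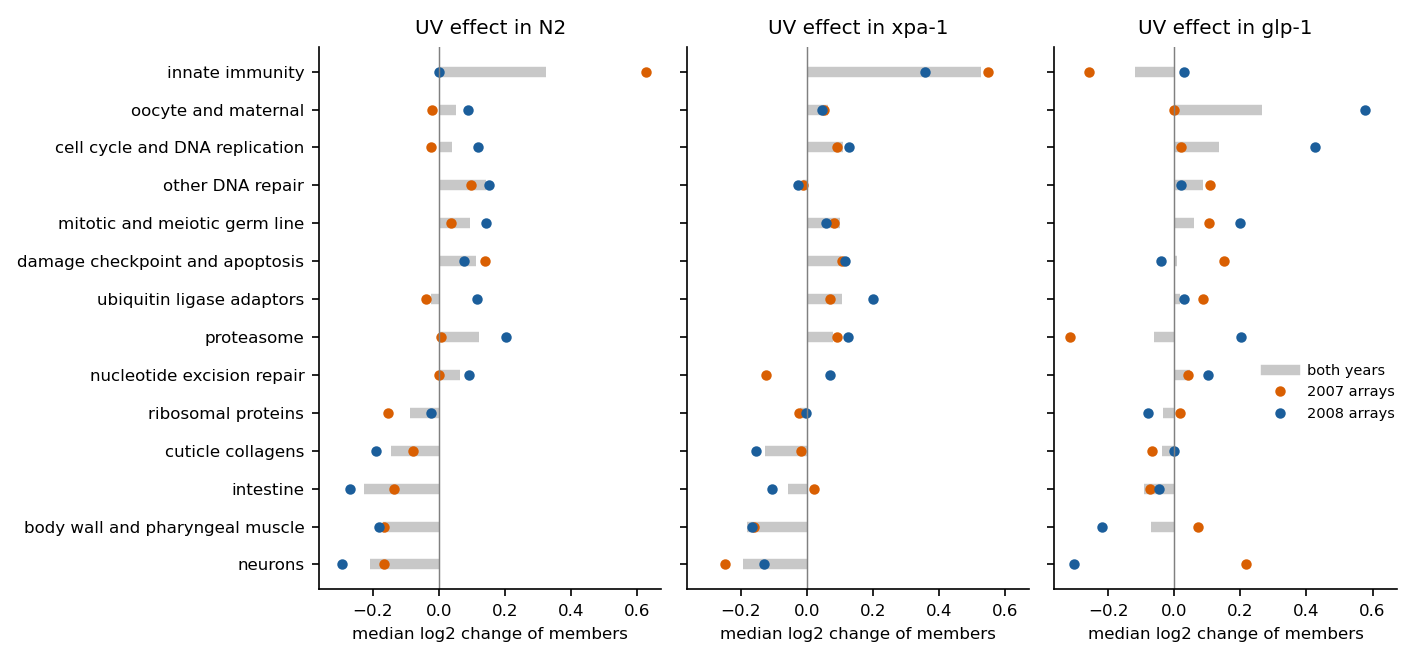
Median log2 change after UV of the members of 14 gene lists in N2, xpa-1 and glp-1, with bars for both years and points for the 2007 and 2008 arrays alone. Innate immunity genes stood at 0.32 in N2, 0.53 in xpa-1 and -0.12 in glp-1, oocyte genes in glp-1 at 0.0000 in 2007 and 0.58 in 2008, and ribosomal protein genes at -0.089 in N2, which turned to 0.12 on values as deposited and to 0.092 with median centring.

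The UV comparison in glp-1 asked which transcripts respond in the soma when the germ line is missing. No gene passed, and germ line genes were among those with the smallest p, each higher in 4 of 4 UV arrays. The germ cell regulator gld-1 was at 5.87 ± 0.69 (n = 4) in controls and 7.98 ± 1.09 after UV, a difference of 2.11 (SE 0.34, adjusted p = 0.1253), with a second probe set at 0.42. The nuclear receptor gene nhr-67 was 1.88 higher, F01G10.4 1.97, the end-joining gene cku-80 1.16 and the eggshell gene cpg-1 1.35 (adjusted p = 0.2700 each). The values were 0.59 for cep-1, 0.47 for ced-13, -0.25 for egl-1, 0.24 for glp-1 and -0.12 for xpa-1, and fbxa-163 and catp-3, which passed in xpa-1, stood at 9.19 and 11.81 in glp-1 controls and at 9.31 and 11.98 after UV. The limma count was 0 with 1637 probe sets at an unadjusted p under 0.05. It was 1 with a trend and robust variances, 76 with array weights, and 137 with 1 weight per year. It was 97 from the 2007 arrays, 159 from the 2008 arrays, 10 without UV 2008-2, 2 without control 2008-2 and 1 without UV 2007-1.

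Oocyte and maternal genes were the 1 list called in glp-1 after UV. Of 39 members 27 were higher and 12 lower, the median was 0.27 (adjusted p = 0.0022; adjusted p = 0.9844 with an estimated correlation), and 4 rose and 1 fell when adjusted over the list alone while 0 passed over all genes. Beside cpg-1, the translational regulator puf-7 was at 1.21 and the oocyte maturation gene oma-2 at 1.06, the latter with 0.0000 in 2007 and 2.12 in 2008. The list median was 0.0000 within 2007 and 0.58 within 2008, and the mean level of the list was 8.22 in the array glp-1 UV 2008-1 against 6.70 to 7.43 in the other glp-1 arrays and 11.20 to 11.74 in N2 and xpa-1 arrays. The call was absent without UV 2008-1 (median 0.033) or control 2008-1 (0.21), which left 0 lists. In contrast 2 to 4 lists were called without each of the other arrays. Adjusted over the list alone, 3 cell cycle genes, 3 mitotic and meiotic germ line genes and 2 checkpoint genes rose, and 2 other DNA repair genes rose and 2 fell, in lists that were not called. Cell cycle genes had a median of 0.14 (adjusted p = 0.0757). By fry 0 lists moved one way (smallest adjusted p = 0.7085) and 4 changed in either direction.

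**Figure D4:**
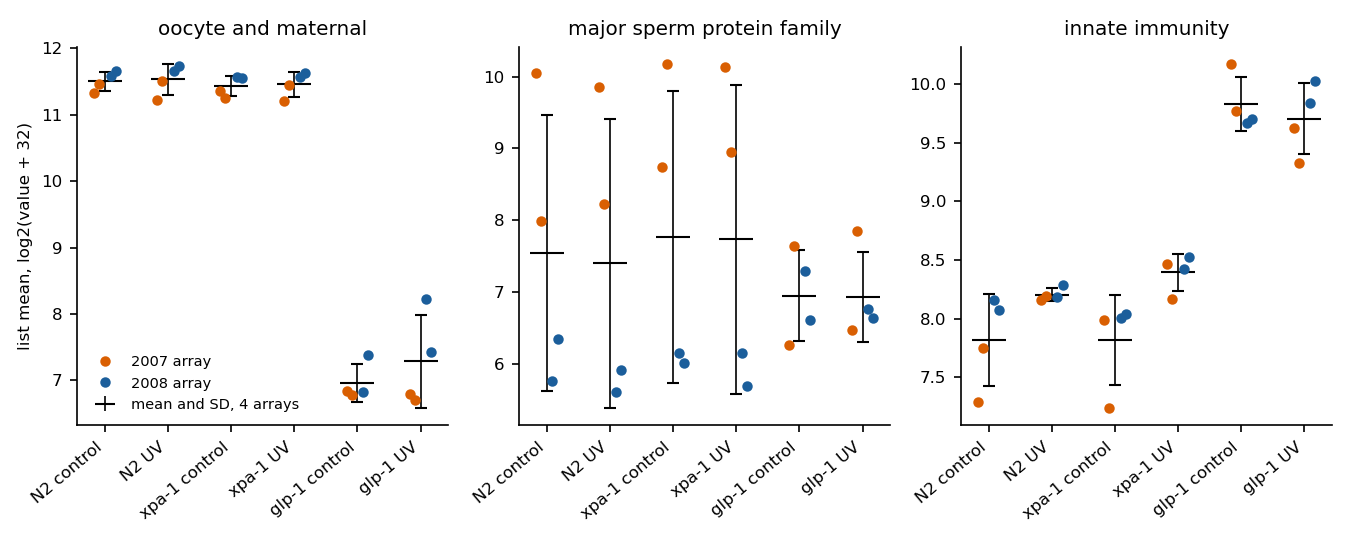
Mean log2 level per array of the oocyte and maternal, major sperm protein and innate immunity lists by group, with 2007 and 2008 arrays as separately coloured points and the mean with SD of 4 arrays. The oocyte mean of the array glp-1 UV 2008-1 was 8.22 against 6.70 to 7.43 in the other glp-1 arrays, and the major sperm protein mean in N2 was 9.03 ± 1.07 in 2007 and 5.91 ± 0.32 in 2008.

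Averaging over strains asked for the mean response of N2, xpa-1 and glp-1, common or not. The genes that rose were F54B8.4 by 1.59 (SE 0.27, adjusted p = 0.0441), catp-3 by 1.54 (SE 0.22, adjusted p = 0.0104) and fbxa-163 by 1.5 (SE 0.19, adjusted p = 0.0051). The catp-3 values were 2.23 in N2, 2.24 in xpa-1 and 0.17 in glp-1, and the difference between glp-1 and N2 did not pass (-2.06, adjusted p = 0.9955). In 2008 alone fbxa-163 was at 1.03, 2.49 and 0.44 in these strains. In all, 7 probe sets were called, 5 higher and 2 lower. They were the 3 genes, a second catp-3 probe set, a probe set of no named gene at 1.57 and 2 shared probe sets of the chloride channel gene clh-1 at -0.55 and -0.53. The brightest clh-1 probe set at -0.48 did not pass (adjusted p = 0.1174). The intestinal acid phosphatase pho-1 was at -0.75 (adjusted p = 0.0553), irg-1 at 1.53 (adjusted p = 0.1267), ced-13 at 0.62 and egl-1 at 0.30. At an unadjusted p under 0.05 stood 1416 probe sets. The count was 13 without glp-1 control 2007-2, 15 without glp-1 UV 2007-1, and 2 to 4 without any other array except glp-1 control 2007-1 and xpa-1 control 2007-2; catp-3 and fbxa-163 were called in all 24 such fits and F54B8.4 in 4 of them. It was 220 from the 2008 arrays, 0 from the 2007 arrays, as deposited or with median centring, 502 with array weights and 508 with 1 weight per year.

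Averaged over strains, 11 lists were called and each lost its call with an estimated correlation (adjusted p = 0.1360 to 0.7465). Innate immunity was up (median 0.20, adjusted p = 3.24e-05), with 3 rises adjusted over the list alone and irg-2 at 1.43. Ubiquitin ligase adaptors were up (0.054, adjusted p = 0.0080), with 3 rises adjusted over the list alone and cul-6 and skr-3 at 0.82 and 0.85. Checkpoint and apoptosis genes (0.073, adjusted p = 0.0290), cell cycle genes (0.13, adjusted p = 0.0038), oocyte genes (0.16, adjusted p = 0.0101) and mitotic and meiotic germ line genes (0.094, adjusted p = 0.0038) were up. The 1 rise adjusted over the list alone in the first and last was gld-1 at 0.80, and other values were cdk-1 at 0.49, rnr-1 at 0.55 and cpg-1 at 0.56. Intestine genes were down (-0.12, adjusted p = 0.0038), with pho-1 as the 1 fall adjusted over the list alone. Muscle (-0.14), neuronal (-0.23) and collagen genes (-0.10) were down (adjusted p = 0.0038, 0.0038 and 0.0047), with unc-22 at -0.42, mec-7 at -0.52 and col-115 at -0.79, and ribosomal protein genes stood at -0.054 (adjusted p = 0.0038), a direction that turned in N2 with 2 scalings. Of xenobiotic metabolism genes 5 rose and 1 fell, and of embryonic zygotic genes 1 fell, when adjusted over the list alone, in lists not called. The oocyte median was 0.0032 within 2007 and 0.29 within 2008. Without glp-1 UV 2008-1 checkpoint (0.028), cell cycle (0.067) and oocyte genes (0.083) were not called, and without xpa-1 UV 2007-2 checkpoint (0.064), oocyte (0.14), ribosomal (-0.022) and muscle genes (-0.079) were not. The checkpoint call was also absent without glp-1 control 2007-1 (0.061), xpa-1 control 2008-1 (0.070), xpa-1 control 2008-2 (0.066) or N2 control 2008-1 (0.051), the oocyte call without glp-1 control 2008-1 (0.12), and the ribosomal call without glp-1 UV 2008-2 (-0.028) or N2 UV 2007-2 (-0.029).

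Whether nucleotide excision repair genes are inducible by UVC was the question most specific to this design. None of the 21 measured genes changed in any strain, over all genes or adjusted over the list alone. The damage sensor subunit ddb-1 was 0.52 higher in N2 (8.42 ± 0.81 to 8.94 ± 0.46, n = 4), 0.60 higher in xpa-1 and at -0.26 in glp-1. The recognition factor xpc-1 was at 0.24, -0.36 and -0.31, the nuclease genes xpf-1 at -0.12, 0.073 and 1.0 and xpg-1 at -0.034, 0.029 and -0.067, and the TFIIH helicase xpb-1 at 0.0021, 0.0030 and 0.046. The transcription-coupled repair genes csa-1 and csb-1 were at 0.65 and 0.12 in N2. The values nearest to passing were rpa-1 (0.79, unadjusted p = 0.0072, adjusted p = 0.5426 by limma) and xpf-1 (unadjusted p = 0.0088, adjusted p = 0.5596) in glp-1. The list median was 0.064 in N2 (camera adjusted p = 0.1354), 0.0030 in xpa-1 (0.8411), 0.046 in glp-1 (0.6133) and 0.019 averaged (0.1792). The averaged list was called from the 2008 arrays alone (median 0.12, adjusted p = 0.0487; adjusted p = 0.5033 with an estimated correlation), where the 2007 median was -0.0011, and also with array weights (0.14), 1 weight per year (0.13), values as deposited (0.24) and median centring (0.19). In N2 the list was called without control 2007-2 (median 0.10, adjusted p = 0.0178), with array weights (0.078), 1 weight per year (0.073), values as deposited (0.34) and median centring (0.32). In xpa-1 it was called on values as deposited (0.43) and with median centring (0.34). Under these 2 scalings 21 and 19 of 32 lists were called in N2 and 20 and 21 in xpa-1, and the median of all probe sets stood at 0.082 and 0.058 in N2 and at 0.14 and 0.053 in xpa-1. With an estimated correlation, computed for all arrays and for the 2008 arrays but in none of the other alternatives, the list was not called in N2 (adjusted p = 0.4485, and 0.6274 in 2008), in xpa-1 (0.9502) or in the average (0.4791). Data were simulated for the N2 comparison with the spread of all strains. Of changes of 1 on the log2 scale 22% were called, of 1.5 58% and of 2 76%.

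**Figure D5:**
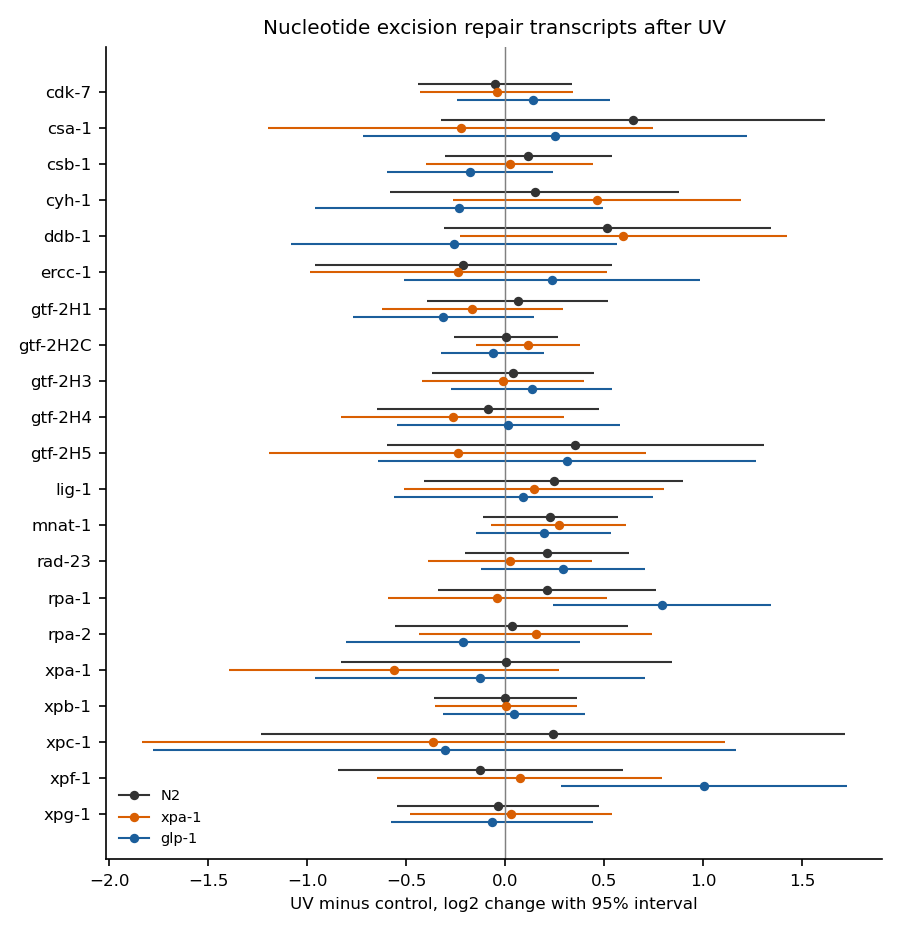
Log2 change after UV (points) with 95% confidence intervals (bars) of each measured nucleotide excision repair transcript in N2, xpa-1 and glp-1, 4 arrays per group. None of the 21 genes was called, and the largest value was 1.0 for xpf-1 in glp-1.

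The differences between strains in the UV effect asked whether loss of xpa-1 or of the germ line alters the response. For xpa-1 against N2 no gene passed: H40L08.2 was at -1.24 (SE 0.28), trpp-5 at -0.95, the neuropeptide flp-10 at -1.28, C46A5.1 at -1.46 and the proline dehydrogenase prdh-1 at -1.78 (adjusted p = 1.0 each). The other values were egl-1 at -1.06, ced-13 at 0.41, cep-1 at -0.18 and the nucleotide excision repair list at -0.053 (adjusted p = 0.6707). The limma count was 0 with 450 probe sets at an unadjusted p under 0.05, the other fits also called 0 probe sets, and 0 lists were called, but 1 without N2 control 2007-1, 2 without xpa-1 UV 2007-2 and 5 without N2 UV 2007-1. The calls of xpa-1 animals are therefore not shown to differ from N2. For glp-1 against N2 no gene passed either: C54C8.3 was at -1.71 (SE 0.33), F31F7.2 at -2.40 (a second probe set at 0.49), gld-1 at 1.97 (a second at -0.24), fbxc-50 at 1.11 and catp-3 at -2.06 (adjusted p = 0.9955 each). The other values were egl-1 at -1.37, ced-13 at -0.026, cep-1 at 0.36 and the nucleotide excision repair list at -0.041 (adjusted p = 0.8565). That count was 0 with 934 at an unadjusted p under 0.05, and 1 from the 2007 arrays.

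Of the lists, 3 differed in UV effect between glp-1 and N2. Innate immunity genes were lower by comparison in glp-1 (median -0.40, adjusted p = 0.0016; adjusted p = 0.9820 with an estimated correlation), with zip-2 at -1.16, irg-2 at -2.26 and clec-67 at -1.36. The median was -0.85 within 2007 but 0.19 within 2008; the call was absent without glp-1 control 2007-1 (-0.31). Proteasome genes were at -0.25 (adjusted p = 0.0016; adjusted p = 0.9820 with an estimated correlation), with rpn-6.2 and pas-7 at -0.92 each. The median was -0.45 within 2007 but -0.0093 within 2008. They were not called without glp-1 control 2007-2 (-0.14), glp-1 UV 2007-1 (-0.086) or N2 control 2008-1 (-0.13). Oocyte genes were at 0.17 (adjusted p = 0.0357; adjusted p = 0.9820 with an estimated correlation), with cpg-1 at 1.18, oma-2 at 0.96 and mei-2 at 0.94. They were not called without glp-1 UV 2008-1 (0.062), N2 control 2007-2 (0.18), N2 UV 2007-1 (0.22), N2 UV 2008-1 (0.17) or glp-1 control 2008-1 (0.20). No member of the 3 lists passed over all genes or adjusted over the list alone; without N2 UV 2007-1 the count of lists was 5, and fry called 0. Adjusted over the list alone, 1 checkpoint gene and 1 mitotic and meiotic germ line gene were higher in lists not called.

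The difference of the UV effect between the years, averaged over strains, asked whether the 2 experiments gave the same response. The effect was more positive in 2008 for fipr-26 (3.3, SE 0.57, adjusted p = 0.0429), F54B11.5 (1.98), the F-box gene fbxa-36 (1.86), F13A7.11 (1.56), the guanylate cyclase gcy-17 (1.47), F53B7.4 (1.32), E03H4.8 (1.3) and the chitinase-like chil-24 (1.28). It was more negative for scav-4 (-1.52), the adenylate cyclase acy-1 (-1.47), chil-16 (-1.26), C28H8.7 (-0.89) and idpa-1 (-0.78). In all 30 probe sets passed, 22 of them positive and 8 negative, for 22 genes, with 1691 at an unadjusted p under 0.05. Called lists were proteasome (0.26), oocyte (0.30), histones (0.25), cell cycle (0.21) and transcription genes (0.19) on the positive side and neurons (-0.24) and somatic gonad (-0.20) on the negative side (adjusted p = 5.02e-07 to 0.0335; adjusted p = 0.2417 to 0.7940 with an estimated correlation). Of their members rpb-2 (0.96) passed over all genes; adjusted over the list alone, 1 transcription and 1 cell cycle gene were positive and 3 somatic gonad genes negative. The number of lists was 12 without N2 UV 2007-2, 3 without glp-1 UV 2007-2, and 4 without glp-1 UV 2008-1, N2 control 2007-2 or xpa-1 UV 2007-1. The proteasome and histone calls were present whichever array was left out. The fit with a replicate block called 10 probe sets. The count was 0 to 16 without any 1 of the 2008 arrays. It was 49 without N2 control 2007-2, 62 and 69 without the xpa-1 UV arrays of 2007, 80 without xpa-1 control 2007-2, 78 and 110 without the glp-1 controls of 2007, and 283 and 244 without the glp-1 UV arrays of 2007.

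Across 10271 genes, which are not independent replicates, the UV effects of N2 and xpa-1 correlated at r = 0.40, with 0.21 within 2007 and 0.60 within 2008. Those of N2 and glp-1 correlated at r = -0.014, with -0.12 within 2007 and 0.41 within 2008, and those of xpa-1 and glp-1 at -0.035, with -0.15 and 0.37. Between the years the UV effect of N2 correlated at 0.21, of xpa-1 at 0.29 and of glp-1 at -0.22. These comparisons share no arrays.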

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

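The tests of germ line tissue, of a UV response in every library, of an intestinal share and of the 2007 spread, the bounds on the innate immunity medians over scalings, and the splits that kept the years or pairs balanced, were chosen after the results were seen. What the reassignments of arrays, the comparison of the oocyte excess over scalings, the sperm covariate and the other splits would have to show was written down before their results were seen. Bounds were revised after results were seen. A split test with a real count of 0 now decides nothing. The test of the 2007 spread in glp-1 had fitted from the 2008 arrays alone and had excluded it from the 2007 arrays alone, and now takes both with the year weights. The germ line test had used the lists in which the excess was found, and now uses other genes. The oocyte difference of 2007 had counted without regard to low signal, and the innate immunity medians had been held against 0 without their spread.

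Single arrays stood apart from the other 3 of their group by Dixon's test in 43 of 806 gene and group pairs, where chance gives about 1 in 20 groups, 40.3 in all. In N2 these were polk-1 10.28 and ttn-1 8.655 (UV 2007-2), and dct-16 11.63, ddb-1 8.26 and idpa-1 5.15 (UV 2007-1). The array N2 control 2007-1 held glp-1 10.40, csa-1 5.53, gtf-2H5 5.00, trcs-1 12.11, cpg-2 13.26, irg-5 5.76 and htp-3 10.19. N2 control 2007-2 held dhs-26 9.52, ftn-1 5.00 and idpa-1 5.08, and N2 control 2008-1 held skr-2 9.47. In xpa-1 they were xpa-1 6.59 and gld-1 12.23 (control 2007-1), his-42 8.88 (control 2008-2), csa-1 5.46 (UV 2007-1), and glp-1 11.15, unc-89 8.68 and fipr-26 5.98 (UV 2007-2). In glp-1 controls they were cdk-1 5.00 and slx-1 5.61 (2007-1), nhr-67 6.17, ins-7 9.57 and sbt-1 10.1044 (2007-2), and cku-80 6.05 and C54C8.3 5.99 (2008-1). The array glp-1 control 2008-2 held oma-2 5.65, cbd-1 6.81, oma-1 5.69, htp-3 5.19 and idpa-1 5.22. In glp-1 after UV they were xpa-1 5.00, egl-1 7.52, irg-2 5.80, F31F7.2 5.00 and unc-47 7.56 (2007-1), C54C8.3 5.29 (2007-2), and glp-1 7.39 and cyh-1 5.26 (2008-1). The cause was not tested.

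Among means of gene lists per array 12 of 192 stood apart, where chance gives 9.6. They were nucleotide excision repair 9.12 (N2 control 2007-1), checkpoint and apoptosis 7.18 (glp-1 UV 2007-1), mitochondrial stress 9.07 and innate immunity 7.24 (xpa-1 control 2007-2), and insulin signalling 9.67 (glp-1 control 2007-2). Others were glycolysis 10.34 and intestine 9.17 (N2 UV 2007-2), ribosome biogenesis 10.33 and intestine 9.07 (xpa-1 UV 2007-2), and ribosomal proteins 12.13 (glp-1 control 2008-1). The last were oocyte genes 7.39 (glp-1 control 2008-2) and mitotic and meiotic germ line genes 6.62 (glp-1 UV 2008-1).

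UV effects differed between glp-1 and N2 for innate immunity (-0.40), proteasome (-0.25) and oocyte genes (0.17). With an estimated correlation these 3 lists were not called (adjusted p = 0.9820 each), and within 2008 the innate immunity median turned to 0.19 and the proteasome median was -0.0093. Between the years they differed for fipr-26 (3.3), F54B11.5 (1.98), fbxa-36 (1.86), F13A7.11 (1.56), gcy-17 (1.47), F53B7.4 (1.32), E03H4.8 (1.3), chil-24 (1.28), ssb-1 (1.26), mdt-11 (1.22) and mog-7 (1.18). Further genes were gldi-8 (1.15), fbxc-35 (1.15), pelo-1 (1.05), Y53F4B.18 (0.98), rpb-2 (0.96) and F58B3.6 (0.92), and on the negative side scav-4 (-1.52), acy-1 (-1.47), chil-16 (-1.26), C28H8.7 (-0.89) and idpa-1 (-0.78). The lists were proteasome (0.26), transcription (0.19), cell cycle (0.21), histones (0.25), oocyte (0.30), somatic gonad (-0.20) and neurons (-0.24). With an estimated correlation 0 of them were called (smallest adjusted p = 0.2417).

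Oocyte and germ line transcripts were higher in the array glp-1 UV 2008-1 than in the other glp-1 arrays of 2008. The normalization was excluded, since the excess of the oocyte mean over the higher control was at least 0.80 on the log2 scale under 5 scalings. Germ line tissue in that library stays open. Of 1083 genes in none of the lists that were over 4-fold lower in glp-1 than in N2 controls of 2007, 50.4% were highest in that array among the 4 of 2008, where 75% had been set as the bound, against 13.2964% to 20.3139% in the others. A UV response in every glp-1 library stays open too: the oocyte mean differed by -0.061 between UV and control in 2007, but only 33.3% of its members exceeded an intensity of 100 there. The array glp-1 UV 2008-2 goes both ways. Its oocyte mean was 7.43 against 6.82 and 7.39 in controls, and its cell cycle median 3.76% of the N2 level against 1.75% and 2.61%. Its mitotic and meiotic median was 2.64% against 2.71% and 3.46%, and its share of highest genes the lowest of the 4. A library with some germ line is a candidate explanation of the oocyte call that was not settled, and no source states how the animals were checked.

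The innate immunity list was called as up after UV in N2 and xpa-1, although no member passed over all genes, the call was absent with an estimated correlation (adjusted p = 0.4216 and 0.0653), and the N2 median within 2008 was 0.0000. Chance order of the arrays within each year was excluded for this list, as 1 of 1296 reassignments, the real one, gave a shift as high. Choice of this list among 32 stays open, because in 82 of 1296 some list had a standardized shift as large. A larger intestinal share stays open: intestine genes were not higher (largest median -0.056), but their own UV response cannot be told from share. Normalization stays open, as does signal: in 2007 both xpa-1 UV arrays had more probe sets over 100 than either control. Quantile normalization within each year lowered the median from 0.53 to 0.37 in xpa-1 and 0.32 to 0.16 in N2. The standard errors (0.0999 and 0.0875) treat genes as independent. By exact permutation within a strain (two-sided, n = 4 and 4) p was 0.0556 in N2 and in xpa-1, the smallest possible, and 0.6111 in glp-1.

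Few probe sets were called for UV over both years. The low signal of 2007 fits for xpa-1: the spread within groups was 2.69 times that of 2008, the 2008 arrays alone called 19 probe sets and the 2007 arrays alone 1. For glp-1 it stays open. For it, 2008 alone called 159, 1 weight per year 137 and array weights 76, against 0 unweighted. Alone, 2007 called 97. Of 126 genes called in 2008, 25 had the same sign in 2007, and UV effects of both years correlated at -0.22. The glp-1 UV arrays of 2007 were the dimmest, so 2007 cannot decide. For N2 it cannot be told, since 1 weight per year called 6 and the 2008 arrays alone 0. The mean of the major sperm protein list as a covariate did not raise the averaged count, which was 5 with it against 7 without. Additive terms for group and year left 37.8% of the variance of that mean. This share includes year differences that varied by strain (3.12 in N2, 3.49 in xpa-1 and 0.23 in glp-1). The covariate therefore does not isolate differences among arrays of the same group and year, and these are not excluded. Stage by other markers was not tested.

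Splits of the same arrays into other groups were fitted in the same way. For glp-1 against N2 controls chance can be excluded for probe sets (8511 against at most 25 in other splits, 1 of 35 as large) but not for the number of lists (22 against 26, 10 of 35). It cannot be excluded for the count of UV in xpa-1 (7 against 7, 2 of 35, and lists 3 against 12, 20 of 35) or the lists of UV in N2 (8 against 17, 13 of 35) and in glp-1 (1 against 12, 35 of 35). Nor can it for the averaged effect (7 against 552, 9 of 100, and lists 11 against 14, 9 of 100), the lists of the glp-1 difference in UV effect (3 against 26, 86 of 100) or the year difference (30 against 139, 8 of 100, and lists 7 against 19, 49 of 100). For xpa-1 against N2 controls the count of 2 (against 3, 2 of 35, and lists 1 against 10, 31 of 35) does not exclude it either. The 2 genes themselves stood apart in every array: xpa-1 at 5.00 to 6.59 in the mutant and 8.92 to 10.07 in N2, and mks-6 at 8.96 to 9.93 and 5.55 to 6.49. Where the real count was 0 every split calls as many, so that the test decides nothing: UV in N2 (highest other 2, 35 of 35), UV in glp-1 (2099, 35 of 35), the xpa-1 difference in UV effect (2, 100 of 100, and lists 15, 100 of 100) and the glp-1 difference (7916, 100 of 100). The high counts point to a structure of the samples by year and strain. The splits that called 7 in xpa-1, 2099 in glp-1 and 3 for xpa-1 against N2 controls set all 2007 arrays against all 2008 arrays, and the year term, shared by all strains, did not remove what was particular to a strain. Within 2007 and 2008 alone UV called 1 and 19 in xpa-1 and 97 and 159 in glp-1, and xpa-1 against N2 controls 2 and 2, which in 2008 were xpa-1 and mks-6 and in 2007 were 2 other probe sets. The split that called 552 also set the years of glp-1 apart, beside exchanges in N2 and xpa-1. That with 7916 exchanged the strains in all UV arrays but in only 1 pair of controls, so that the strain difference entered. That with 139 exchanged the years in all UV arrays of glp-1 and N2, but in no glp-1 control and 1 pair of N2 controls, and in 1 pair each of xpa-1 control and UV arrays.

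Every fit held a year term, but many of these splits mix the years unevenly. Among the 18 splits with 2 arrays of each year in each group, which are too few for a share under 0.05, the highest other count was 0 against 7 for UV in xpa-1, 0 against 2 for xpa-1 against N2 controls and 25 against 8511 for glp-1 against N2 controls. For lists it was 12 against 3, 10 against 1 and 26 against 22. In UV in N2 it was 1 against 0 (lists 17 against 8) and in UV in glp-1 82 against 0 (lists 9 against 1). For the averaged effect 17 of the 100 splits were balanced so, with at most 1 probe set against 7 and 13 lists against 11. Balance did not remove high counts everywhere, since the glp-1 difference still had 7916 against 0 (lists 25 against 3) among 28 balanced splits, and the xpa-1 difference 2 against 0 (lists 15 against 0) among 29. By their correlations alone, which no label backs, the replicate numbers were taken to pair the arrays of UV in N2 (0.10 and 0.31) and in glp-1 (0.16 and 0.46), and of the splits 8 part every pair, again too few. In N2 these called at most 0 probe sets against 0 and 5 lists against 8, and in glp-1 at most 82 probe sets against 0 and 9 lists against 1; the other splits join paired arrays in a group.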

How the results depend on the processing

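The alternatives chosen after seeing the data are named above, and all others were chosen before. Where a value moved the cause was not tested. Counts are probe sets called, and lists are gene lists called of 32.

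Without a year term UV in xpa-1 had 3 calls and 1 list, UV in glp-1 2 lists, the averaged effect 3 calls and xpa-1 against N2 0 lists. A year term per strain gave 54 calls for xpa-1 against N2. With the compared groups alone UV in N2 had 1 call, UV in xpa-1 0, UV in glp-1 0 lists, and xpa-1 against N2 1 call and 0 lists. With an adjusted p of 0.01 UV in xpa-1 had 2 calls and the averaged effect 1.

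The 2007 arrays alone gave UV in N2 2 lists, UV in xpa-1 1 call and 1 list, UV in glp-1 97 calls, and the averaged effect 0 calls and 1 list. The glp-1 difference in UV effect had 1 call, xpa-1 against N2 0 lists and glp-1 against N2 4296 calls. The oocyte median then shrank without turning negative in UV in glp-1 (0.0000), in the averaged effect (0.0032) and in the glp-1 difference (0.022), as did that of cell cycle genes in the averaged effect (0.059), while camera's direction was down and not called. The 2008 arrays alone gave UV in N2 16 lists, UV in xpa-1 19 calls and 10 lists, UV in glp-1 159 calls and 14 lists, and the averaged effect 220 calls and 20 lists. The xpa-1 difference had 3 lists, the glp-1 difference 5, with innate immunity turned to 0.19, and xpa-1 against N2 4 lists.

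On values as deposited UV in N2 had 21 lists, UV in xpa-1 0 calls and 20 lists, UV in glp-1 13 lists, the averaged effect 0 calls and 21 lists, the glp-1 difference 14 lists, and xpa-1 against N2 1 call and 15 lists. With median centring UV in N2 had 19 lists, UV in xpa-1 0 calls and 21 lists, UV in glp-1 14 lists, the averaged effect 0 calls and 19 lists, the glp-1 difference 19 lists, and xpa-1 against N2 0 calls and 19 lists. Ribosomal proteins in N2 after UV turned to 0.12 and 0.092 in these fits. Quantile normalization within each year gave UV in xpa-1 0 calls and 8 lists, UV in glp-1 2 lists, the averaged effect 4 calls, the xpa-1 difference 1 list, the glp-1 difference 5 lists, xpa-1 against N2 0 calls and 3 lists, and the year difference 123 calls. With 75th percentile scaling UV in xpa-1 had 4 calls, UV in glp-1 0 lists and the averaged effect 3 calls. In glp-1 against N2 it turned rps-19 to 0.31, rpl-27A to 0.25 (0.2450) and the ribosomal list to 0.40.

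Trend and robust variances gave UV in N2 2 calls, UV in xpa-1 11, UV in glp-1 1 and the year difference 9. Array weights gave UV in N2 25 calls and 18 lists, UV in xpa-1 262 and 12, UV in glp-1 76 and 12, the averaged effect 502 and 20, the xpa-1 difference 4 lists, and xpa-1 against N2 4 calls and 3 lists. With 1 weight per year UV in N2 had 6 calls and 18 lists, UV in xpa-1 149 and 11, UV in glp-1 137 and 11, the averaged effect 508 and 21, the xpa-1 difference 5 lists, and xpa-1 against N2 5 calls and 6 lists. With log2(value + 1) UV in N2 had 5 lists, UV in xpa-1 2 calls and 1 list, UV in glp-1 4 calls and 2 lists, the averaged effect 0 calls, xpa-1 against N2 1 call and 0 lists, and the year difference 65 calls. With the dimmest 40% left out the year difference had 17 calls.

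With a replicate block, UV in N2 and in glp-1 had 0 calls each, UV in xpa-1 9, the averaged effect 8, both differences between strains 0, xpa-1 against N2 3, glp-1 against N2 8446 and the year difference 10.

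With an estimated correlation 12 lists were called for glp-1 against N2, and by fry 25. Every other comparison had 0 by either. With the mean over probe sets UV in glp-1 had 3 lists.

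With each array left out in turn, the number of calls ranged from 2 to 9 for UV in xpa-1, 0 to 10 for UV in glp-1, 2 to 15 for the averaged effect, 2 to 3 for xpa-1 against N2, 7661 to 8220 for glp-1 against N2 and 0 to 283 for the year difference. It stayed at 0 for UV in N2 and both differences between strains. The number of lists ranged from 3 to 12 for UV in N2, 1 to 9 for UV in xpa-1, 0 to 4 for UV in glp-1, 8 to 15 for the averaged effect, 0 to 5 for the xpa-1 difference, 2 to 5 for the glp-1 difference, 0 to 3 for xpa-1 against N2, 19 to 23 for glp-1 against N2 and 3 to 12 for the year difference.

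Of the values of named genes 11546 kept their side of the limit, called or not, 81 moved past it, 381 no longer passed and 2 turned, and of those of lists 1648, 16, 268 and 8. Arrays measure relative signal, and the 2007 arrays, of which 5.85% to 19.5% of probe sets exceeded an intensity of 100, limit what can be called for transcripts of low level.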

Other observations

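The fits of the 2008 arrays alone were planned, and the comparisons of their calls with 2007, their lists with an estimated correlation and the sperm tests were chosen after the results were seen. The 2008 arrays, fitted alone by limma, called more probe sets for UV in xpa-1, in glp-1 and averaged over strains than both years together, and 0 in N2. Averaged over strains 220 probe sets passed, 128 higher and 92 lower, for 174 genes. The poly(ADP-ribose) glycohydrolase gene parg-2 rose by 2.60 (SE 0.34, adjusted p = 0.0257), the cytochrome P450 gene cyp-14A5 by 2.34 (adjusted p = 0.0060), irg-2 by 2.14 (adjusted p = 0.0199), ugt-26 by 1.98 (adjusted p = 0.0078), the P-glycoprotein pgp-8 by 1.76 and the antimicrobial peptide cnc-4 by 1.75. The transporter amt-4 fell by 1.48 (adjusted p = 0.0027), D2023.1 by 1.39, scav-4 by 1.0 and ugt-12 by 0.91. In 2007 D2023.1 and scav-4 had the opposite sign (0.36 and 0.51), amt-4 and ugt-12 the same (-0.98 and -0.36), and the 6 named rises were at 0.092 (cnc-4) to 1.22 (pgp-8). Of the 174 genes 64.4% had the same sign in 2007, where unrelated years would give about 50%, and 18 of them had that sign at an unadjusted p under 0.05 there. The median of the higher genes was 0.71 in 2008 and 0.092 in 2007. In xpa-1 19 probe sets passed, of which 12 of 15 genes had the same sign in 2007, and in glp-1 159, of which 25 of 126 genes did. In glp-1 the genes higher in 2008 had a median of 1.17 there and of -0.60 in 2007. The genes named here were picked after their values were seen and stand for no group: of 177 xenobiotic metabolism genes 6 rose and 1 fell and the list was not called (median 0.0000, adjusted p = 0.7557), and the innate immunity list (2 of 41 rose, median 0.073, adjusted p = 0.0052) was not called with an estimated correlation (adjusted p = 0.1745). The 1 UV list of 2008 called with an estimated correlation was intestine in N2, which was lower (median -0.27, adjusted p = 7.02e-07; adjusted p = 0.0266 with an estimated correlation; median -0.14 in 2007), with 0 members passing. The array glp-1 UV 2008-1 enters these counts, with an oocyte mean of 8.22 against 6.82 and 7.39 in the glp-1 controls of 2008, so part of them may come from germ line transcripts in that library, where 50.4% of 1083 other germ line genes were highest among the glp-1 arrays of 2008.

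Sperm transcripts differed between the years in the strains with a germ line. In N2 the mean of the major sperm protein list was 9.03 ± 1.07 in 2007 and 5.91 ± 0.32 in 2008 (n = 4 each, difference 3.12, exact permutation two-sided p = 0.0286, the smallest possible, adjusted over 9 tests p = 0.0429). In xpa-1 it was 9.5005 ± 0.76 and 6.01 ± 0.22 (difference 3.49), and in glp-1 7.06 ± 0.81 and 6.83 ± 0.32 (exact p = 0.6571). Other sperm genes followed, at 6.73 ± 0.37 and 5.88 ± 0.06 in N2 and 6.77 ± 0.19 and 5.90 ± 0.05 in xpa-1. Oocyte genes in N2 were at 11.38 ± 0.13 in 2007 and 11.66 ± 0.06 in 2008. Year is also labelling kit, so stage and kit cannot be told apart, and the sperm covariate left 5 averaged UV calls.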
